A study of Rattus norvegicus with 13 samples.

How the data were processed

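Fat from 13 female rats was profiled on Affymetrix arrays with biotin-labelled cRNA, 1 array per animal, 7 from control fathers and 6 from fathers fed a high-fat diet, with groups and sample numbers taken from the sample titles. The deposited table holds log2 values of 29214 probes. Per the submitters' processing notes the authors used RMA, which corrects background, normalizes between arrays and summarises the probes of a set on the log2 scale, and Partek, an analysis package, and the versions, the order of the steps and any filter are not given in the sources used here. The log2 scale was read from the values, which run from 3.24 to 14.54 in all columns. RMA forces the arrays toward a common distribution, and differences in overall spread that remain can move dim and bright genes in opposite directions. No scanner files were used here, so background and detection per probe were not assessed. No 2 arrays were near copies, with pairwise correlations of 0.946 to 0.995 and at most 607 identical values in a pair.

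Probes were named from the platform annotation, in which 15633 probes are listed, 15310 with 1 gene symbol and 323 with several, and 13581 probes of the table are not listed and stay unnamed. Entrez identifiers of 15279 probes were found in the RefSeq gene table of assembly GRCr8, and 0 symbols needed updating. The build behind the array is not given in the sources used here, so no coordinates are printed. Probes with 1 symbol were used, and for 527 genes with several probes the probe with the highest mean over all arrays was kept, which left 14506 genes. No filter on dim probes was set.

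Groups were compared with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and with no covariate, since the labels give no batch, litter or pairing. Differences are high-fat minus control in log2 units, with limma's moderated standard error. Beside the adjusted count, the count of genes with an unadjusted p under 0.05 was kept as a description of signal.

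Before the data were examined, 41 gene lists were written down, covering adipocyte function, metabolism, stress and regulation, 2 receptor families, other cell types and tissues that a piece of fat could hold, and Y-linked genes as a check of labels. The 40 lists other than the Y-linked one were tested with camera at its preset correlation of 0.01, and again with the correlation estimated from the data and with fry, each adjusted over the lists. Camera asks whether the genes of a list shift relative to other genes. Fry asks whether they move on balance in one direction. For fixed lists, p-values were also adjusted over the list alone. The median of each list was set against 10000 random lists of other genes drawn from the same 20 bins of mean level. The lists share members, such as Fabp4, Lipe and Plin1 in the adipocyte and lipolysis lists and Sdha in the citric acid cycle and oxidative phosphorylation lists.

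The rule for named genes was also set before the data were examined. It takes all genes that pass if fewer than 20 do, the 8 higher and the 8 lower genes with the smallest unadjusted p leaving out names that are only locus numbers, 2 to 4 members with the smallest p from each list described, and Adipoq, Lep, Pparg, Slc2a4 and Ucp1 in any case. Genes outside the rule were named after their values were seen.

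Single measures per array were compared with two-sided exact permutation tests over 1716 arrangements. Correlations across arrays used 100000 permutations, or all arrangements within a group, and 7 relations were computed and adjusted together. After seeing the data, the mean of each receptor list was also set against other genes of the same level bins across arrays, in a linear model with group as a term. Other settings chosen before the data were examined were renewed quantile normalization, centring each array on its median, only genes above the middle of the mean levels, the mean of the probes of a gene, an intensity trend with robust variance, array weights, the number range as a covariate, leaving out each array, all probes, an unmoderated model, an adjusted p of 0.1 and the 2 other list tests. Added after seeing the data were the standard deviation of each array and the muscle level as covariates, alone and together, fits without the 3 arrays of smallest spread (controls 658 and 631 and high-fat 660), fits without the 4 arrays with most muscle signal (controls 662 and 664, high-fat 629 and 619), and fits within each number range.

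The steps were tested on simulated data with independent noise and the real group sizes. In 5 sets with 200 changed genes each among 14506, limma recovered 19.7% of genes changed by 0.25 log2 units, 79.7% of those changed by 0.5 and 94.8% of those changed by 1. In 20 sets, camera called a list raised by 0.2 each time and made 2 calls among the other lists, under noise that is not correlated between genes as real noise is. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.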

Results

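Gene expression was measured in the fat of female Sprague Dawley rats, an outbred laboratory strain, whose fathers had eaten either pellets with 43% fat or standard chow with 9% fat. The fathers were mated at 15 weeks of age with females that ate chow. The daughters themselves were weaned onto chow at 3 weeks, and their fat was taken at 14 weeks. Of 13 daughters with 1 array each, 7 had a control father and 6 a high-fat father. The labels name each daughter by a number between 619 and 631 or between 656 and 664, which is used as the sample name here. The deposited values were log2 levels of 29214 probes per array, between 3.24 and 14.54, with array medians of 7.66 to 7.72, and the number of arrays limits the precision of every comparison. Nothing in the labels says which daughters shared a father or a litter, so the p-values measure the spread between these samples. They treat the daughters as independent and may be too small if daughters of a group shared a father or a litter. The comparison addressed how the diet of the father bears on gene expression in the fat of daughters that did not eat that diet and that, per the series description, handled glucose less well at a similar weight and adiposity.

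Daughters of high-fat fathers had slightly higher levels of genes for fatty acid beta-oxidation, the citric acid cycle and oxidative phosphorylation. They had slightly lower levels of lymphocyte, mesothelial and chemosensory receptor genes. Each difference was seen over a whole gene list and not in single genes, and was called only with a preset correlation between genes. The median log2 difference, high-fat minus control, was 0.21 for fatty acid beta-oxidation, 0.17 for the citric acid cycle and 0.11 for oxidative phosphorylation. It was -0.13 for T and NK cell genes, -0.28 for mesothelial genes and -0.22 for olfactory receptors. Random lists of other genes of the same level as the 3 oxidation lists also stood higher, with a median of 0.08 for each. The olfactory median was -0.01, and not called, with the spread of values of each array as a covariate, and the T and NK cell median was -0.01, and not called, without the 4 arrays with most skeletal muscle signal. In daughters 656 to 664 alone the mesothelial list was the only one of the 6 called in the same direction, and in daughters 619 to 631 alone it was the only one not called. These 6 lists passed limma's camera test with its preset correlation between genes, and none of them passed when that correlation was measured in the data (adjusted p = 0.51 for each with an estimated correlation). No gene passed limma's test, with 0 of 14506 genes past an adjusted p of 0.05 and a smallest adjusted p of 0.53, and an unmoderated linear model also gave 0. At an unadjusted p under 0.05, limma gave 1155 genes, 786 higher and 369 lower, and the unmoderated model gave 1075. With each array centred on its median, 82.9% of such genes were higher, against 68.1% without centring. The threshold alone would give 725.3 genes on average. Other splits of these arrays into groups of the same sizes gave a median of 480 genes, from 63 to 3289. Of 100 splits, the real one included, 14 reached 1155, so chance cannot be excluded for this count.

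The count of 1155 genes rested on single arrays. It was 508 without high-fat daughter 624, 591 without high-fat 619, 593 without high-fat 620, 682 without control 658 and 713 without control 631. It was 1774 without control 622 and 2508 without high-fat 660. Within the daughters numbered 619 to 631, 3 control against 4 high-fat, 1990 genes had such a p (879 higher and 1111 lower), and within those numbered 656 to 664, 4 against 2, only 135 did.

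Of 40 gene lists, 21 passed an adjusted p of 0.05 in limma's camera test with its preset correlation between genes of 0.01, 10 of them higher and 11 lower in the high-fat group. None of these calls held with an estimated correlation, where 0 lists passed and the smallest was an adjusted p = 0.40 with an estimated correlation. The fry test also passed 0 lists, with a smallest adjusted p of 0.29, and at an unadjusted p under 0.05 the counts were 1 list with the estimated correlation and 5 lists by fry. Over all genes tested, 0 members of any list passed limma's test. Set against 10000 random lists of other genes of the same level, 10 of the 21 medians lay within the range that holds 95% of the random lists, at the percentiles given for adipocyte identity (92.91), insulin signalling (81.61), telomere maintenance (54.01), chromatin (61.67), oxidative stress defence (59.53), endothelium (78.98), kidney tubule (12.24), exocrine pancreas (30.7), ovary and uterus (63.75) and mammary epithelium (73.4). Lipolysis lay at percentile 97.51, oxidative phosphorylation at 99.96, beta-oxidation and the citric acid cycle at 100, B and plasma cells at 0.53, neutrophils and mast cells at 0.22, and T and NK cells, mesothelium, immediate early genes and both receptor lists at 0. Lists that camera did not call lay as far out. Erythroid cells lay at 100, brown and beige fat at 99.97, and ribosomal proteins, macrophages, preadipocytes, extracellular matrix, smooth muscle and skeletal muscle at 0. The random lists carry no correlation between genes, so extreme percentiles alone single out no list.

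The 8 genes with the smallest p and a higher level in the high-fat group did not pass. Among them, Aco1, the cytosolic aconitase that also acts as an iron regulatory protein, had a log2 level of 11.11 ± 0.10 (SD, n = 7) in control and 11.38 ± 0.11 (SD, n = 6) in high-fat daughters, a difference of 0.27 ± 0.06 (SE). All 6 high-fat daughters lay above all 7 controls for Aco1, and the same was true of Mrpl21, a protein of the mitochondrial ribosome (0.22 ± 0.05), and Hmox2, the constitutive heme oxygenase (0.23 ± 0.06). Genes chosen for the smallest p of all genes tested tend to part the groups in this way, so the separation is no further evidence. Aldh6a1, a mitochondrial enzyme of valine breakdown, differed by 0.25 ± 0.06, Ndufaf1, an assembly factor of respiratory complex I, by 0.32 ± 0.08, and Rsad2, an antiviral protein induced by interferon, by 0.42 ± 0.10. Ctdspl, a phosphatase, differed by 0.31 ± 0.07 and N5 by 0.29 ± 0.08. Each of these 8 genes had an adjusted p of 0.53.

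Among the 8 genes with the smallest p and a lower level in the high-fat group, 3 were olfactory receptors, Or1n1b (-0.29 ± 0.07), Or52m1 (-0.33 ± 0.10) and Or4p20b (-0.30 ± 0.09). Angptl1, a secreted protein related to angiopoietins, had the largest difference of these, -0.41 ± 0.11, with levels of 8.32 ± 0.25 (SD, n = 7) and 7.91 ± 0.15 (SD, n = 6). Drd1, a dopamine receptor, differed by -0.27 ± 0.06, Usp44, a deubiquitinase, by -0.20 ± 0.05, Tesl by -0.18 ± 0.05 and Gapdh-ps1 by -0.20 ± 0.06. Levels of Usp44 and Tesl, also chosen by their p, were lower in all 6 high-fat daughters than in any control. These genes were dim. Mean levels in control and high-fat daughters were 6.81 and 6.54 for Drd1 and 6.72 and 6.52 for Usp44. They were 6.07 and 5.89 for Tesl and 6.86 and 6.66 for Gapdh-ps1. The Y-linked Sry read 6.38 to 6.62 in these female samples, and signal over background was not assessed. The adjusted p of each was again 0.53.

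Genes of fatty acid beta-oxidation, the citric acid cycle and oxidative phosphorylation stood higher as lists. Part of this was shared with other genes of the same level, whose random lists had a median of 0.08. The medians were 0.21 for beta-oxidation, 0.17 for the citric acid cycle and 0.11 for oxidative phosphorylation. Of 25 measured beta-oxidation genes, 24 had a higher and 1 a lower mean in the high-fat group, and 7 had an unadjusted p under 0.05, all higher. Adjusted over the list alone, 3 passed, Acads (0.22 ± 0.06), Hadh (0.36 ± 0.10) and Echs1 (0.20 ± 0.06), enzymes that act on short- and medium-chain substrates, and over all genes tested 0 passed. The mean of the list was 10.12 ± 0.20 (SD, n = 7) in controls and 10.33 ± 0.26 (SD, n = 6) in high-fat daughters, with 5 of 6 high-fat arrays above the control mean. The list rose by camera, but not with its correlation measured in these arrays (adjusted p = 0.51 with an estimated correlation). Of 20 citric acid cycle genes, 19 were higher and 8 had an unadjusted p under 0.05. Dld, a subunit shared by the pyruvate and oxoglutarate dehydrogenases (0.25 ± 0.07), passed adjusted over the list alone, while Ogdh (0.17 ± 0.05) and Suclg2 (0.17 ± 0.06) did not (adjusted p = 0.51 for the list with an estimated correlation). Of 68 nuclear-encoded subunits of oxidative phosphorylation, 64 were higher and 7 had an unadjusted p under 0.05, none of which passed adjusted over the list alone. Ndufb8 differed by 0.17 ± 0.06, Cox6a1 by 0.16 ± 0.06 and Sdha by 0.21 ± 0.09 (adjusted p = 0.51 for the list with an estimated correlation).

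The meaning of the 2 ranges of sample numbers is not given, and the medians were not close in them. In daughters 619 to 631 the median differences were 0.34 for beta-oxidation, 0.31 for the citric acid cycle and 0.18 for oxidative phosphorylation. In daughters 656 to 664 they were 0.05, -0.02 and -0.03, the calls of the first and second list were lost, and the last was called in the opposite direction. The arrays with most muscle signal were high-fat 619 and 629 in the first range and controls 662 and 664 in the second, and the median of the muscle list moved the same way, 1.74 and -2.35. The difference between the ranges was not itself tested. With the number range as a covariate the 3 medians were 0.21, 0.16 and 0.09, and without the 4 arrays with most muscle signal 0.19, 0.17 and 0.10, each called with the preset correlation. The beta-oxidation median was 0.14 without high-fat daughter 629.

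Genes that mark the adipocyte and its handling of fat also leaned higher. Of 26 adipocyte identity genes 23 were higher, with a median of 0.09, and of 20 lipolysis genes 17 were higher, with a median of 0.11, and both lists passed camera (adjusted p = 0.51 for each with an estimated correlation). The adipocyte median lay within the range of random lists of the same level (0.03 to 0.10 for 95% of them), and that of lipolysis just above the upper bound of its own (0.11). In each list, 0 genes passed adjusted over the list alone. The members with the smallest p were in both lists, Fabp4, the fatty acid carrier of adipocytes (0.20 ± 0.06), Lipe, hormone-sensitive lipase (0.16 ± 0.05), and Plin1, the coat protein of the lipid droplet (0.18 ± 0.06). The call of the adipocyte list was lost in daughters 619 to 631 alone, where its median was 0.09, and both calls were lost among genes in the upper part of the expression range, with medians of 0.09 and 0.11. Adiponectin (Adipoq) differed by 0.04 ± 0.06, leptin (Lep) by 0.10 ± 0.28, Pparg, the master regulator of adipocyte differentiation, by 0.09 ± 0.07 and Slc2a4, the insulin-responsive glucose transporter, by 0.18 ± 0.17. None of these 4 passed, with adjusted p of 0.76, 0.87, 0.56 and 0.62 in limma.

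Of 28 insulin signalling genes 26 were higher, with a median of 0.10, and the list passed camera (adjusted p = 0.51 with an estimated correlation). Pdpk1 (0.14 ± 0.05), the insulin receptor Insr (0.20 ± 0.08) and Akt2 (0.15 ± 0.07) had the smallest p, and 0 genes passed adjusted over the list alone. The median lay within the range of random lists of the same level (0.05 to 0.11 for 95% of them). The list's call was lost when the values were quantile-normalized again (median 0.07), among genes in the upper part of the expression range (0.11) and in daughters 656 to 664 alone (0.05). Fatty acid and triglyceride synthesis did not pass camera, with 17 of 25 genes higher and a median of 0.07. It was called without control 658 (0.13), without high-fat 620 (0.11), with array spread as a covariate (0.10), without the 3 arrays of smallest spread (0.11) and in daughters 619 to 631 (0.15), against a median of -0.01 in daughters 656 to 664. With an estimated correlation it passed neither over all arrays (adjusted p = 0.64 with an estimated correlation) nor with the spread as a covariate (0.68). Its median was 0.00 without high-fat 629 and 0.04 without control 622 or control 627. Adjusted over that list alone, 2 genes passed, Dgat1, which makes the last step of triglyceride synthesis (0.20 ± 0.05), and Pck1, the glyceroneogenic enzyme (0.19 ± 0.05), and over all genes tested 0 passed.

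**Figure D1:**
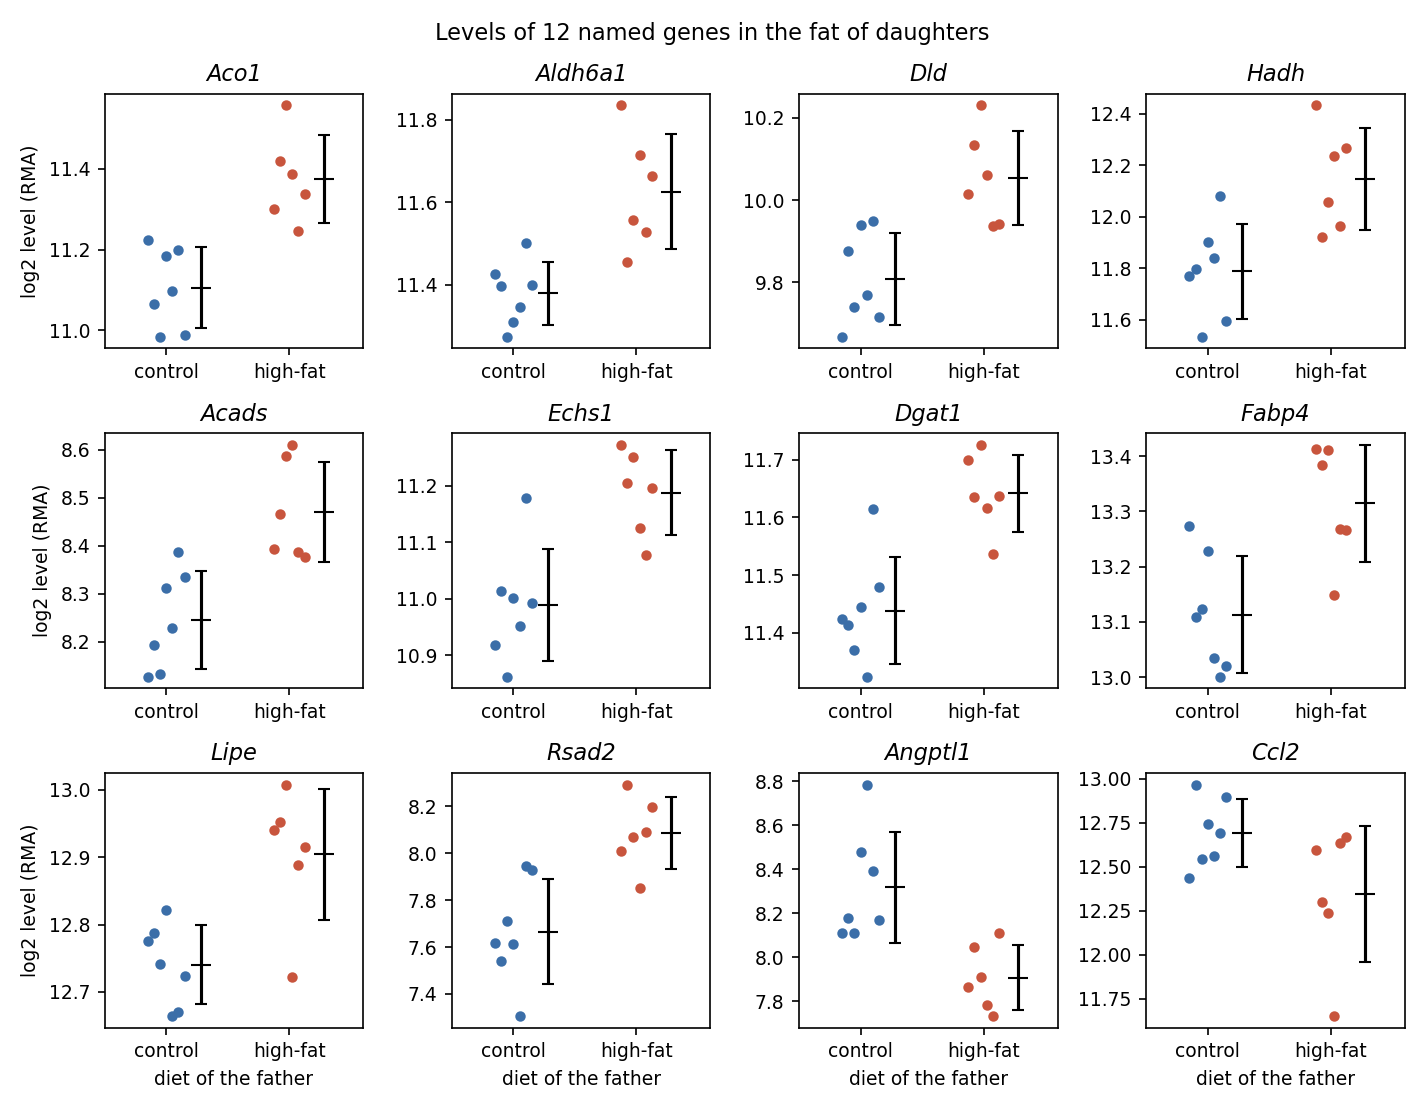
Log2 levels of 12 named genes in each daughter (points; y axis, log2 RMA level; x axis, diet of the father; control n = 7, high-fat n = 6), with the mean and SD of each group as a horizontal tick and bar. For Aco1, chosen by its small p, all 6 high-fat daughters lie above all 7 controls, and none of the 12 genes passed limma's test over all genes.

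Of the immune lists, those of T and NK cells, neutrophils and mast cells, and B and plasma cells were lower. All 25 measured T and NK cell genes had a lower mean in the high-fat group, with a list mean of 7.48 ± 0.19 (SD, n = 7) in controls and 7.34 ± 0.11 (SD, n = 6) in high-fat daughters. The list fell by camera but not with the correlation of these arrays (adjusted p = 0.51 with an estimated correlation). Cd3d, a chain of the T cell receptor complex, differed by -0.18 ± 0.07, Cd28, its costimulatory receptor, by -0.32 ± 0.15 and Gzmb, granzyme B, by -0.29 ± 0.14. Cd3d was dim, with mean levels of 6.19 in control and 6.02 in high-fat daughters. The neutrophil and mast cell list also fell by camera, with 16 of 20 genes lower and a median of -0.09 (adjusted p = 0.40 with an estimated correlation). Its leading members were Hdc, the histamine-forming enzyme (-0.23 ± 0.08), Mmp8 (-0.18 ± 0.07) and Mmp9 (-0.16 ± 0.07). Mmp8 (6.15 in control and 5.97 in high-fat daughters) and Mmp9 (6.70 and 6.54) were dim too. B and plasma cell genes had a median of -0.09 with 11 of 15 lower, among them Fcrla (-0.28 ± 0.12), and passed camera (adjusted p = 0.51 with an estimated correlation). In these 3 lists 0 genes passed adjusted over the list alone.

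The median of the T and NK cell list was -0.08 without control daughter 664 and -0.01, with its call lost, without the 4 arrays that held most skeletal muscle signal. The B cell call was lost without high-fat daughter 619 (-0.06), without those 4 arrays (-0.04) and with array spread as a covariate (-0.05), and the median of the neutrophil and mast cell list was -0.03 without control 627 and -0.15 without high-fat 663. In daughters 656 to 664 alone none of the 3 lists was called, with medians of -0.04 for T and NK cells, 0.01 for neutrophils and mast cells and 0.00 for B cells.

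Macrophage genes (25 measured, median -0.02) and inflammatory cytokines and adhesion molecules (28 measured, 14 higher and 14 lower) did not pass camera (adjusted p = 0.77 and 0.60 with an estimated correlation). The calls of these 2 lists given next used the preset correlation. The median of the cytokine list was 0.01 and its mean -0.04, and camera, which sets a list against the other genes, gave the direction as lower. Without control 658 both lists were called lower, with medians of -0.06 and -0.03. Among genes in the upper part of the expression range camera also called both lower, with medians of -0.02 and 0.04. All genes in that part had a median of 0.0852, so lower there means relative to the other genes. The macrophage list was called lower too with array spread as a covariate (-0.09), after renewed quantile normalization (-0.05) and in daughters 619 to 631 (-0.12). With that covariate it did not pass under an estimated correlation (adjusted p = 0.83 with an estimated correlation). The macrophage median turned in daughters 656 to 664 (0.09, not called), without control 622 (0.03), control 631 (0.01) or high-fat 619 (0.03) and with each array centred on its median (0.01). The cytokine list was also called with array weights and without the 3 arrays of smallest spread (-0.06). Cytokine genes with the smallest p were 3 chemokines that attract monocytes, Ccl7 (-0.48 ± 0.18), Ccl2 (-0.34 ± 0.15) and Ccl3 (-0.26 ± 0.10), and 0 of the list passed over all genes or adjusted over the list alone. Immediate early genes had a median of -0.06, with Egr2 at -0.28 ± 0.10, and passed camera (adjusted p = 0.51 with an estimated correlation). That call was lost without control 664 (-0.03), with the number range as a covariate (-0.04), in daughters 619 to 631 (-0.03) or 656 to 664 (-0.02) alone and without the 4 muscle-bearing arrays (-0.00), and the median was -0.10 without control 631.

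Of 14 genes of the mesothelium, the cell layer over visceral fat, 13 were lower, with a list mean of 8.22 ± 0.38 (SD, n = 7) in controls and 7.96 ± 0.29 (SD, n = 6) in high-fat daughters. The list fell by camera (adjusted p = 0.51 with an estimated correlation), and 0 genes passed adjusted over the list alone. Bnc1 differed by -0.37 ± 0.17, Rspo1 by -0.34 ± 0.22 and Krt18 by -0.27 ± 0.12 on its brightest probe, while other Krt18 probes gave -0.10 ± 0.09 and 0.00 ± 0.11. The call was lost in daughters 619 to 631 alone, where the median was -0.06.

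Chemosensory receptors, a family expressed mainly in the nose, formed the largest list and were dim, with a mean level of 5.96 for olfactory receptors. Of 1105 olfactory receptor genes, 1077 were lower and 28 higher in the high-fat group, 151 lower and 1 higher at an unadjusted p under 0.05, and 0 passed over all genes or adjusted over the list alone. Of 134 vomeronasal receptor genes, 127 were lower, with a median of -0.16, Vom1r100 (-0.15 ± 0.05) having the smallest p. Both lists fell by camera (adjusted p = 0.51 for each with an estimated correlation). The olfactory list was written down with knowledge that published work on such animals names these receptors, so its direction is not independent evidence.

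The olfactory receptor level followed the spread of values of each array. Across 13 arrays, the median olfactory receptor level fell with the standard deviation of all probes (r = -0.973, rho = -0.962, permutation p = 1e-05 for each, the smallest that 100000 permutations can give). The Benjamini-Hochberg adjusted p was 3.5e-05 over the 7 relations computed. Leaving out controls 658 and 631, the arrays farthest from the median spread, r was -0.945 (permutation p = 9e-05). Within the 7 controls r was -0.965 (exact permutation p = 0.00238) and within the 6 high-fat arrays -0.981 (exact permutation p = 0.00139). Within daughters 619 to 631 r was -0.982 and rho -1 (exact permutation p = 0.000198 and 0.000397), and within daughters 656 to 664 r was -0.964 and rho -0.829 (exact permutation p = 0.0125 and 0.0583). The spread was 1.89 ± 0.05 (SD, n = 7) in controls and 1.93 ± 0.04 (SD, n = 6) in high-fat daughters, a difference of 0.043. Such a difference was not rare when the arrays were regrouped (two-sided exact permutation p = 0.124 over 1716 arrangements). With the spread as a covariate, the median of the olfactory receptors was -0.01 and that of the vomeronasal receptors 0.01, and neither was called. In daughters 656 to 664 alone the medians were 0.02 and 0.02, neither called, and without control 658 they were -0.14 and -0.09. Without the 3 arrays of smallest spread they were -0.15 and -0.09, both still called with the preset correlation. After renewed quantile normalization the vomeronasal median was -0.09, also still called.

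With the same covariate, the medians of beta-oxidation (0.17), the citric acid cycle (0.13), oxidative phosphorylation (0.05), adipocyte identity (0.07), lipolysis (0.07), T and NK cells (-0.13), mesothelium (-0.18) and neutrophils and mast cells (-0.12) were still called by camera, as was that of the immediate early genes (-0.06). None of these 9 passed with the same covariate and an estimated correlation (adjusted p = 0.34 to 0.89 with an estimated correlation). The insulin signalling (0.03) and B and plasma cell (-0.05) lists were not called with the preset one either. With the muscle level as a further covariate, the calls of mesothelium (-0.16) and of the immediate early genes (-0.04) were lost as well, and the medians of adipocyte identity, lipolysis and oxidative phosphorylation were 0.05, 0.05 and 0.05, still called with the preset correlation and not with an estimated one.

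**Figure D2:**
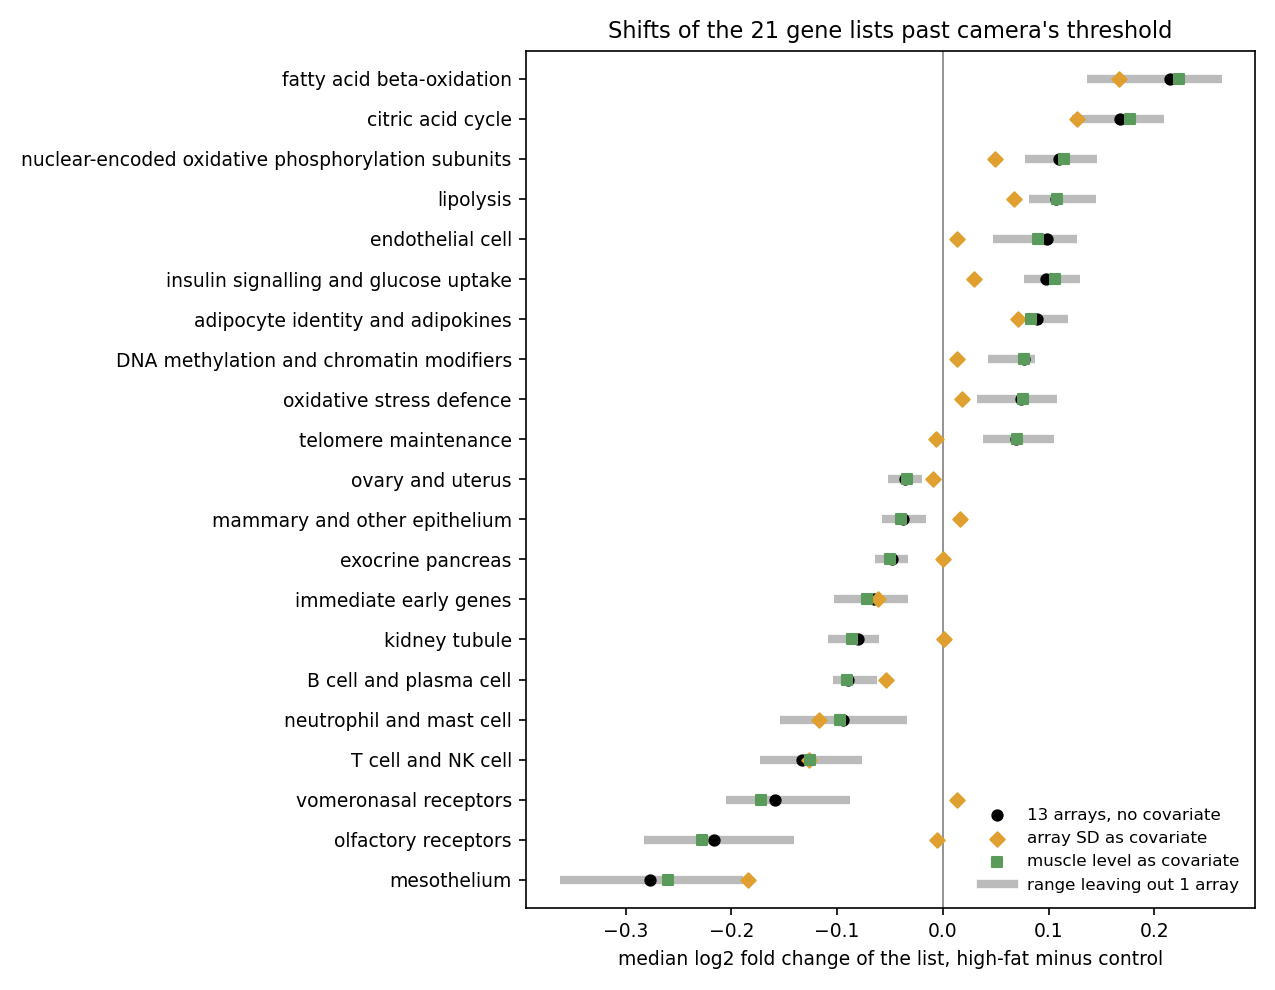
Median log2 difference, high-fat minus control (x axis), of the 21 gene lists that passed camera with its preset correlation, over all 13 arrays (black circles), with the standard deviation of each array as a covariate (orange diamonds) and with the skeletal muscle level as a covariate (green squares); grey bars span the medians when 1 array was left out. With the spread as a covariate the olfactory receptors lie at -0.01 and beta-oxidation at 0.17.

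Skeletal muscle genes were high in 4 arrays, from both groups. The mean of 21 muscle genes was 11.63 in control 662, 11.49 in control 664, 11.44 in high-fat 629 and 8.93 in high-fat 619, against 7.12 to 7.26 in the other 9 arrays. The group means were 8.43 ± 2.14 (SD, n = 7) and 8.16 ± 1.75 (SD, n = 6) and did not differ by more than this spread (two-sided exact permutation p = 0.801). With the muscle level as a covariate the beta-oxidation median was 0.22. The muscle list did not pass camera, with a median of -0.13, but its median was 1.74 in daughters 619 to 631 and -2.35 in daughters 656 to 664. When 1 array was left out, the list was called lower in 7 of 13 fits, and its median ran from -0.88 without high-fat 629 to 0.41 without control 662. Ucp1, the uncoupling protein of brown adipocytes, was 11.02 in high-fat 629, 10.96 in high-fat 663, 9.76 in control 662 and 9.28 in control 658, and 6.1 to 7.4 in the other 9 arrays. It differed by 0.48 ± 0.96 between the groups, and its sign turned without high-fat 629 (-0.14) or high-fat 663 (-0.13). The brown and beige fat list had a median of 0.11 and did not pass, and its median was 0.01 without high-fat 629 and -0.00 without high-fat 663.

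**Figure D3:**
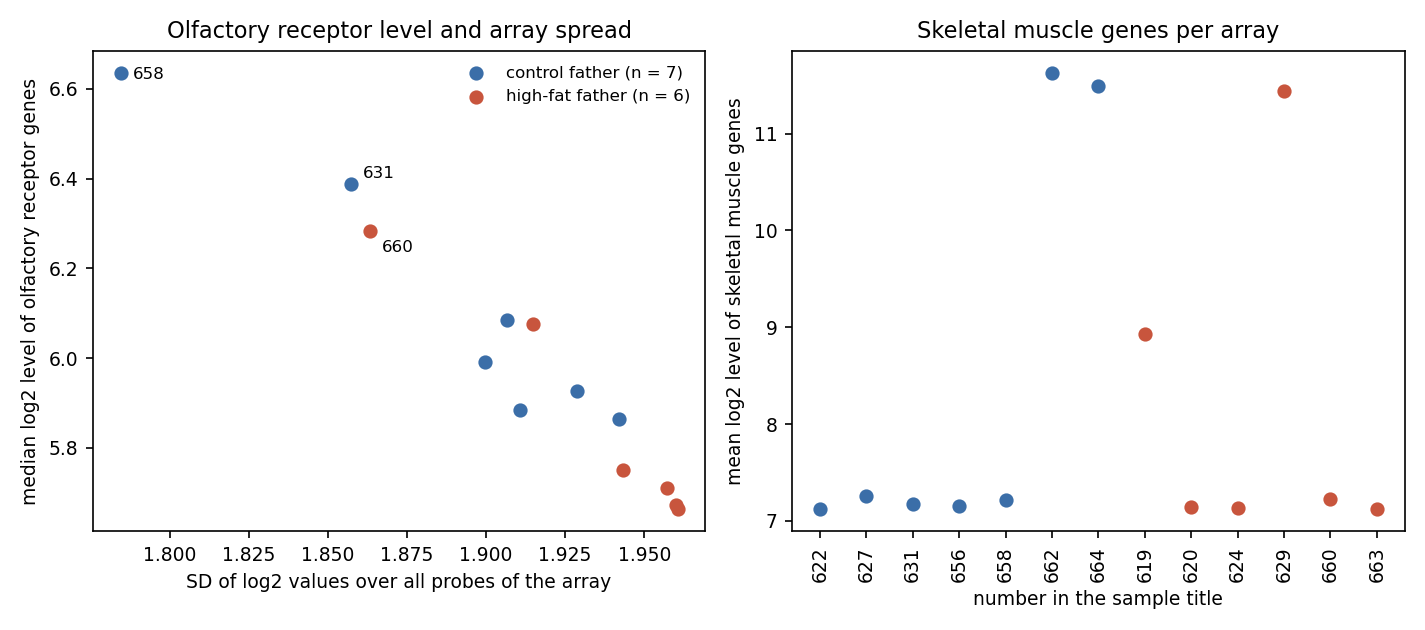
Left, median log2 level of the olfactory receptor genes (y axis) against the standard deviation of all log2 values of an array (x axis), 1 point per array, blue for control fathers (n = 7) and red for high-fat fathers (n = 6). Right, mean log2 level of 21 skeletal muscle genes in each array, by sample number; controls 662 and 664 and high-fat 629 lie above 11, high-fat 619 at 8.93 and the others below 7.3.

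Further lists passed camera with small medians. All 24 telomere maintenance genes were higher, with a median of 0.07 and Nbn, a DNA repair protein at telomeres, at 0.19 ± 0.06, and this list too was chosen knowing published work on such animals. DNA methylation and chromatin genes (39 of 42 higher, median 0.08) and oxidative stress defence genes (27 of 30 higher, median 0.07) also passed, with the peroxiredoxin Prdx3 at 0.20 ± 0.08 (adjusted p = 0.60 for each of these 3 lists with an estimated correlation). Endothelial genes had a median of 0.10 with Sox18 at 0.28 ± 0.13 (adjusted p = 0.64 with an estimated correlation), and their call was lost without control 658 (0.05), control 662 (0.08), high-fat 620 (0.08) or high-fat 660 (0.08). Without control 658 the medians of the telomere, chromatin and oxidative stress lists were 0.04, 0.04 and 0.03, and without high-fat 660 that of the telomere list was 0.11. None of these 4 lists was called with the spread as a covariate (medians -0.01, 0.01, 0.02 and 0.01) nor among genes in the upper part of the expression range (0.08, 0.08, 0.09 and 0.10), and the chromatin, oxidative stress and endothelial calls were also lost after renewed quantile normalization (0.05, 0.05 and 0.05). In daughters 656 to 664 alone the telomere (0.01), chromatin (0.04) and oxidative stress (0.04) calls were lost, and in daughters 619 to 631 alone the endothelial one (0.04). The medians of all 4 lists lay within the range of random lists of the same level.

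Lists of other tissues also passed camera, at low levels on the array. Medians were -0.08 for kidney tubule, -0.05 for exocrine pancreas, -0.04 for mammary and other epithelium and -0.04 for ovary and uterus (adjusted p = 0.51 for each with an estimated correlation). None of the 4 was called with the spread as a covariate, and their medians were 0.00, 0.00, 0.02 and -0.01. Renewed quantile normalization turned the sign of the pancreas (0.00), mammary (0.03) and ovary (0.02) medians. The mammary call was also lost without any 1 of controls 627 (-0.03), 631 (-0.04) and 658 (-0.02) or high-fat 619 (-0.03), 629 (-0.04) and 663 (-0.03), and the ovary call without controls 658 (-0.02), 662 (-0.03) or high-fat 663 (-0.03). With the number range as a covariate the mammary (-0.03) and ovary (-0.02) calls were lost too.

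The other lists did not pass camera. Their medians were 0.07 for glycolysis, 0.10 for cholesterol synthesis, 0.06 for the unfolded protein response, 0.09 for the circadian clock, -0.02 for the cell cycle, 0.06 for apoptosis, 0.06 for imprinted genes and 0.00 for ribosomal proteins. They were -0.01 for preadipocytes and fibroblasts, -0.03 for extracellular matrix, -0.21 for smooth muscle, 0.00 for the adrenal gland, 0.18 for erythroid cells and 0.02 for nerve. Single arrays carried part of these values. Calls given here for fits without 1 array used the preset correlation. Over all arrays the adjusted p with an estimated correlation was 0.51 for smooth muscle and 0.69 for cholesterol synthesis. It was 0.76 for the unfolded protein response and extracellular matrix and 0.77 for preadipocytes. Without control 658 the smooth muscle median was -0.04, those of the unfolded protein response, apoptosis and imprinted genes were 0.01, 0.01 and 0.03, and the preadipocyte (-0.06) and extracellular matrix (-0.07) lists were called. Smooth muscle was called, at -0.20 to -0.26, without any 1 of controls 631, 662 and 664 and high-fat 619 and 620. Glycolysis turned to -0.05 without high-fat 629. Cholesterol synthesis was called without any 1 of controls 631 and 656 and high-fat 619, 620 and 660 (0.10 to 0.13), and its median was 0.05 without control 658 or high-fat 624. The erythroid median ran from 0.11 without high-fat 663 to 0.27 without high-fat 619. With the preset correlation the erythroid list was called with the number range (0.30) or array spread (0.20) as a covariate and in daughters 656 to 664 (0.32). With array spread it did not pass under an estimated correlation (adjusted p = 0.68 with an estimated correlation). Also called was the unfolded protein response without any 1 of controls 631, 656 and 664 and high-fat 660 (0.05 to 0.08). The small medians of the preadipocyte, extracellular matrix, cell cycle, ribosomal protein, adrenal and nerve lists each changed sign in at least 1 fit that left out an array. The median (0.02) of the nerve list and its camera direction differed in sign. Of 10 Y-linked symbols written down to check that samples were female, 2 were measured, Sry at 6.38 to 6.62 and Tspy1 at 5.66 to 5.84 over the 13 arrays, with no array apart. Both were near the level of the dim olfactory receptors and no male sample was measured, so the check cannot decide the sex.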

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

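The fits with array spread or muscle level as a covariate and both tests of the muscle signal were chosen only after the result was seen, as were the bound for the number range, the comparison of receptors with other dim genes across arrays, the look at what the highest split parts and the decision to read the random-list percentiles together with the spread covariate. The matched random lists, the Ucp1 covariate and the splits of the samples were set before their results were seen.

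Olfactory and vomeronasal receptors, 1105 and 134 genes with little reason to be active in fat, were lower in nearly all members in the high-fat group. Muscle in the sample is argued against as the cause, since the olfactory median stayed at -0.2275 with the muscle level as a covariate. A shift of all dim probes by the same amount is argued against as the whole cause. Other genes of the same level moved by -0.06336 (95% of 10000 random lists between -0.0687 and -0.0570) against -0.2168 for the olfactory receptors, a value between the bounds set for either case. Across the 13 arrays, with group as a term, the olfactory mean changed by 2.919 log2 units per unit of those other genes (95% interval 1.964 to 3.875) and the vomeronasal mean by 2.084 (1.706 to 2.461), where a common shift gives 1. Those other genes fell in the high-fat group too, so the shift was not of the receptors alone. With the spread of each array as a covariate the median was -0.005766, so a difference in the spread of values between arrays may account for much of the shift. This covariate follows the receptors themselves so closely (r = -0.973, and -0.952 when the spread was taken without receptor probes) that the direction of the link stays open. Without the 3 arrays of smallest spread the olfactory median was still -0.146. After renewed quantile normalization, which gives all arrays the same distribution, the vomeronasal median was still -0.093. Both were called with the preset correlation, so spread is not shown to be the whole cause. An effect of the diet of the father on these genes stays open and untested, since the groups overlapped in spread (exact permutation p = 0.124) and 1 array, control 658, had the narrowest spread.

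Beta-oxidation and citric acid cycle genes were higher in the high-fat group, with medians of 0.21 and 0.17, and both lists lay at percentile 100 of 10000 random lists of the same level. The uncalled erythroid list also lay at 100, and the random lists carry no correlation between genes, so this percentile does not single out the oxidation lists. Array spread as the whole cause is argued against by the medians of 0.17 and 0.13 left with it as a covariate, still called by camera. Muscle is argued against by the beta-oxidation median of 0.2237 with the muscle level as a covariate. With the Ucp1 level as a covariate that median was 0.1574, above the bound set for brown adipocytes as the cause. Brown adipocytes stay open as part of it, since the beta-oxidation mean was highest in the arrays with the highest Ucp1. It was 10.72 in high-fat 629, 10.54 in control 662 and 10.53 in high-fat 663, with Ucp1 at 11.02, 9.76 and 10.96. Control 658 went the other way, with Ucp1 at 9.28 and a beta-oxidation mean of 10.18. That mean was below those of high-fat 619 (10.28) and 624 (10.27), with Ucp1 at 6.42 and 6.37. For oxidative phosphorylation, at percentile 99.96, spread cannot be told apart from a change of the genes, since its median went from 0.11 to 0.05 with the covariate, and the bound set for the percentile was too weak, as the olfactory receptors lay at percentile 0 of the same test while the covariate removed their shift. Chance between animals stays open, because neither list passed with an estimated correlation (adjusted p = 0.51 for each), and so do unlabelled litters or fathers. A difference between the 2 number ranges as the whole cause is argued against by the beta-oxidation median of 0.2109 and the citric acid cycle median of 0.16 with the range as a covariate, both still called with the preset correlation. Within the ranges beta-oxidation had medians of 0.34 and 0.05, but the muscle list moved the same way there (1.74 and -2.35). Muscle and whatever the ranges stand for, which the labels do not say, are therefore not separated in the contrast between ranges. A higher oxidative gene level in daughters of high-fat fathers may be taken as a hypothesis only.

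Skeletal muscle genes were high in 4 arrays, 2 of each group, with Myh4, a fast muscle myosin, at 12.31 in control 662, 12.72 in control 664, 13.25 in high-fat 629 and 10.85 in high-fat 619 against 6.53 to 6.99 in the other 9. Of the 21 muscle genes, 17 were higher in each of the 4 arrays than in any other array, which muscle tissue in the dissected piece may explain. A sample of another tissue under a wrong label is argued against, since the adipocyte list mean was only 0.039 log2 units lower there (-0.039). The muscle list mean did not differ between the groups by more than the spread between arrays (exact permutation p = 0.801), which leaves an effect of the diet of the father neither shown nor excluded.

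A sample far from the others of its group, by its gap to the nearest sample relative to the range of the group, was found in 16 of 226 tests of a group, where chance gives about 1 in 20. Control 658 gave 8 of them, with list means of 10.84 for lipolysis, 9.912 for oxidative stress defence, 9.565 for endothelial cells and 10.94 for smooth muscle and pericytes, and levels of 6.997 for Drd1, 11.9 for Akt2, 7.727 for Blnk and 8.83 for Sox18. Control 662 stood apart for the citric acid cycle (11.19) and control 664 for the cell cycle (7.219). High-fat 629 stood apart for glycolysis (11.08) and Adipoq (13.64), high-fat 619 for macrophages (10.24) and high-fat 663 for neutrophils and mast cells (7.544). Control 627 stood apart for Cd3d (6.476) and control 622 for Mmp8 (5.859).

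Other splits of the 13 samples into groups of 7 and 6 were drawn, 100 with the real one included. For the genes past an adjusted p of 0.05 the real count was 0, which any split reaches (100 of 100, the highest other with 2), so the splits say nothing there. Chance cannot be excluded for the genes with an unadjusted p under 0.05, where 14 of 100 splits reached the real 1155 and the highest other gave 3289, a count that points to a structure of the samples other than the diet. The 6 arrays of that split (controls 622, 631, 658 and 664, high-fat 660 and 663) had a smaller spread of values than the other 7 (difference in SD -0.0591, exact permutation p = 0.0181, of 3 measures looked at), and over the 99 other splits the count rose with the difference in spread between their groups (rho = 0.72), so array spread may be part of that structure, as may be true of the 1155, which became 407 with it as a covariate. For the lists past camera, 4 of 100 splits, the real one and 3 that tie with it, reached the real 21, and the highest other also gave 21. That share is under the 5 in 100 set before, by a narrow margin and with ties, in a single draw of splits that treats the daughters as independent. The bound was met, but this does not exclude chance for the count. It does not bear on any single list, as 0 passed with an estimated correlation. The other splits still had a median of 14 called lists and never fewer than 7, so camera's preset correlation calls many lists in these samples whatever the grouping.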

How the results depend on the processing

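The fits with array spread or muscle level as covariates, without the narrowest or the muscle-bearing arrays, and within 1 number range were chosen after seeing the data. No gene passed an adjusted p of 0.05 in limma in any of the 30 alternatives run, and none of the 72 named genes passed in any of their 1990 alternatives; 12 of these, over 7 genes, had the other sign. The count of genes with an unadjusted p under 0.05, 1155 over all arrays, was 661 among genes above the middle of the mean levels (641 higher and 20 lower; fewer genes tested), 2092 over all probes (more probes tested), 2179 with array weights, 611 with the number range as a covariate, 407 with array spread, 493 with spread and muscle level, 550 without the muscle-bearing arrays, 1990 in daughters 619 to 631 and 135 in daughters 656 to 664 (fewer samples), and 508 to 2508 when 1 array was left out. Centring each array gave 82.9% higher among such genes, against 68.1%, the fit without the 3 narrowest arrays 51.5% and daughters 619 to 631 alone 44.2% (879 higher and 1111 lower). Except where stated, the cause was not tested.

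The 21 lists past camera became 0 with an estimated correlation, 0 by fry, 13 with both covariates, 9 in daughters 656 to 664 and 14 among genes above the middle of the mean levels, and were 19 to 24 when 1 array was left out. Of those 14, 3 were higher and 11 lower and 7 were among the 21; 7 of the 21 had too few genes left there, and 7, all higher, lost their call with medians of 0.077 to 0.11, against a median over all genes left of 0.0852 (0.0258 over all 14506). Renewed quantile normalization also gave 21, but 6 higher and 15 lower against 10 and 11, of which 15 were among the 21. Of 560 alternatives of the 21 lists, 471 kept direction and call, and 16 lists kept them in every fit that left out 1 array. Under the spread covariate 9 of the 21 kept their call. Of 510 alternatives of the 19 uncalled lists, 75 gave a call, and 77 others had a median of the other sign with no call. With both a covariate and an estimated correlation, 0 lists passed.

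Camera's direction turned in daughters 656 to 664 for oxidative phosphorylation (-0.032, called), the citric acid cycle (-0.017), glycolysis (-0.068, called), olfactory receptors (0.023), B cells (0.00022), extracellular matrix (0.12, called) and kidney tubule (0.042), and in daughters 619 to 631 for skeletal muscle (1.74, called). It turned with spread, and with spread and muscle level, for telomere maintenance (-0.0067 and -0.0018), vomeronasal receptors (0.013 and 0.0083) and mammary epithelium (0.016 and 0.010), with both covariates for endothelial cells (-0.0079), and with renewed quantile normalization for mammary epithelium (0.025). The median alone crossed 0 in daughters 656 to 664 for vomeronasal receptors (0.023), neutrophils and mast cells (0.012) and pancreas (0.0086), with renewed quantile normalization for pancreas (0.0031) and ovary (0.022), and with spread for kidney tubule (0.00076). The cause was not tested. Signal over background could not be assessed from summarised values, which limits what can be said of dim genes. No paired analysis was possible because the groups share no replicate numbers.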

Other observations

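All 3 lists below were written down after the genes with the smallest p had been seen, leaving those genes out, and the covariate fit was chosen after seeing the data. The percentile tests were set before their results were seen. The remaining members can still move together with the genes left out, and the random lists carry no correlation between genes. A high percentile is therefore not independent evidence for any of these lists. Each list stood higher in the high-fat group, 0 genes of any list passed limma's test over all genes tested, and 1155 genes overall had an unadjusted p under 0.05.

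Enzymes that break down branched-chain amino acids were higher in 19 of 21 measured genes, with a median of 0.16 and 7 genes with an unadjusted p under 0.05, all higher. Pccb, a subunit of propionyl-CoA carboxylase, differed by 0.28 ± 0.08 (SE), Auh, of leucine breakdown, by 0.24 ± 0.07, Bckdha, of the branched-chain ketoacid dehydrogenase, by 0.24 ± 0.09 and Ivd, isovaleryl-CoA dehydrogenase, by 0.17 ± 0.07. The hypothesis that this pathway is higher in daughters of high-fat fathers was tested against 10000 random lists of the same level, and the median lay at percentile 100. With the spread of each array as a covariate the median was 0.08, at percentile 99.99. The list did not pass with an estimated correlation (p = 0.091 with an estimated correlation), so the hypothesis stays open.

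Interferon-stimulated genes other than Rsad2 were higher in 30 of 32 measured, with a median of 0.18, at percentile 100 of the random lists. Parp9 differed by 0.28 ± 0.11 (SE), Eif2ak2, the kinase that senses double-stranded RNA, by 0.22 ± 0.09 and Stat2, a transcription factor of the interferon response, by 0.22 ± 0.10. With the spread as a covariate the median was 0.04, at percentile 99.4, and p = 0.27 with an estimated correlation, so a difference in array spread may account for most of it and the hypothesis of a higher interferon response stays open.

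Mitochondrial ribosomal proteins other than Mrpl21 were higher in 59 of 64 genes, with a median of 0.11 at percentile 99.94. Mrps35 differed by 0.26 ± 0.08 (SE) and Mrpl46 by 0.19 ± 0.07. With the spread as a covariate the median was 0.00, at percentile 53.1, and p = 0.30 with an estimated correlation, so the shift of this list may come from array spread and the hypothesis of a higher level found no support beyond it.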
